A study of Mus musculus with 3 samples.

How the data were processed

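Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in pancreatic epithelial spheroids of mice. Per the labels' protocols, each lysate came from 5e7 cells fixed in 1% formaldehyde for 10 min and was immunoprecipitated with 10 µg of antibody. The series holds 3 libraries: an input of untreated spheroids, an H3K27ac library of untreated spheroids and an H3K27ac library of spheroids derived after caerulein treatment of the mice. Each H3K27ac library has 1 peak list, and no peak list or signal of the input was used here.

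The submitters' processing notes name Trimmomatic 0.38, Bowtie2 2.2.6, SAMtools and MACS 1.4, with the builds GRCm38 and mm10, 2 names for the same assembly. The peak names in the deposited lists are those that MACS gives, and each list belongs to 1 library, so peaks were not called on pooled samples. Which control library and which options the caller was given is not given in the sources used here. Each row of a deposited list holds a chromosome, a start, an end, a peak name and a score. The deposited score runs from 50.0 to 3233.06 and piles up at 3100, where 5828 post-caerulein and 8440 untreated peaks lie at or above that value. No header defines the score. It was used only to rank and filter peaks within 1 list, because a caller's score depends on the depth of its library. The lists give no read counts, so the depth of the libraries is unknown. Of the peak numbers, 5 are skipped in the untreated list and 0 in the post-caerulein list.

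All peaks on chromosomes 1 to 19, X and Y were used (38793 post-caerulein and 37765 untreated). Peaks of the lists were compared with an overlap of at least 1 bp, checked against bedtools 2.31.1. A peak without any overlap in the other list is called post-caerulein-only or untreated-only. Protein-coding genes (21887) came from a RefSeq table of GRCm38.p6, the build of the lists. That table gives the start and end of each gene but neither strand, exons nor transcription start sites. The planned promoter analysis was therefore replaced by gene ends: a gene counted as marked when a peak lay within 1 kb of either of its ends. As a check of the build, a peak covered an end of 51.0% of genes in the untreated list, against 17.3% when the genes were shifted by 50 kb. Of the genes marked in both lists, 73.2% had only 1 end covered in each. Peaks were assigned to the gene with the nearest end within 100 kb, and a peak over the ends of several genes was counted once, for the gene that comes first on the chromosome. Positions inside exons, introns or untranslated regions were not analysed here. The planned search for transcription factor motifs needs the genome sequence and was not run.

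With 1 library per group there is no replicate error, and no p-value was computed. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error over peaks only. For 16 gene lists (379 measured genes; 6 listed symbols are not used in the annotation), the mean over genes of post-caerulein-only minus untreated-only peaks was placed among 10000 random gene lists of the same size. Random lists were matched on the number of peaks assigned to each gene after merging the 2 lists. A list was said to stand apart below percentile 2.5 or above percentile 97.5, which describes these 2 libraries only. By chance 5% of lists stand apart. Covered length was summed over peaks within 50 kb of either gene end, and its log2 ratio used a pseudocount of 1 kb. Tested on simulated data, the overlap was recovered for 100% of 32269 simulated sites. The simulated sites lay apart and both copies of a shared site kept its middle, so this outcome was fixed by the setting. It checks the overlap code only and says nothing about adjoining or fragmented peaks. With the list-only labels drawn at random, 3.5% of 200 simulated lists of 25 genes stood apart. With 90% of the members' list-only peaks drawn as post-caerulein-only, 77.0% did. Both draws treated peaks as independent and took members only from genes with at least 1 assigned peak. Real list-only peaks came in runs at single genes, so these rates may be too favourable.

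Named genes followed a rule fixed before the data were examined, together with the gene lists, the comparisons and most alternatives. The use of gene ends in place of transcription start sites was settled once the annotation had been seen. Leaving out predicted genes (Gm numbers and Rik names), the rule takes the 10 genes per direction with most list-only peaks of one list and none of the other, ties going to the highest own-list score among these peaks. It adds the 5 highest-scored list-only peaks, the 5 highest-scored gene-end peaks seen in 1 list alone, the 5 widest peaks of each list, and up to 4 members of each gene list with the largest difference. Equal scores among list-only peaks were ordered by width, a choice made after the scores had been seen. Gene-end peaks tied in score came in the order of gene symbols instead. Alternatives changed the overlap rule, the score threshold, merging, chromosomes, the gene-end window (2.5 kb), the assignment limit (10 kb or none), the matching and the list statistic. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.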

Results

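H3K27ac was compared between pancreatic spheroids of untreated mice and spheroids of mice that had earlier received caerulein, a cholecystokinin analogue that causes acute pancreatitis. The comparison asks whether the epithelium carries a different set of active regulatory regions after the inflammation has passed. Spheroids are three-dimensional epithelial cultures, here of wild-type C57BL/6J mice. Each condition has 1 H3K27ac library, so no difference below has a replicate check and no p-value is given. The post-caerulein list held 38793 peaks covering 140.4 Mb, with a median width of 2495 bp. The untreated list held 37765 peaks covering 134.6 Mb, with a median width of 2483 bp. Sequencing depth is unknown.

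Most H3K27ac regions were found in both conditions. An untreated peak overlapped 32001 of the 38793 post-caerulein peaks, and 6792 (17.51%, exact 95% interval 17.13 to 17.89) were post-caerulein-only. Of the untreated peaks, 5402 (14.30%, 13.95 to 14.66) were untreated-only. List-only peaks were narrow, with median widths of 1464 bp (post-caerulein) and 1536 bp (untreated) against 2809 bp and 2697 bp for shared peaks. They also had low scores: 72.7% of post-caerulein-only and 68.5% of untreated-only peaks lay in the lowest 25% of scores of their own list. Among peaks at or above the median score of their list, the balance turned to the untreated side, with 183 post-caerulein-only peaks (0.94%, 0.81 to 1.09) and 304 untreated-only peaks (1.61%, 1.44 to 1.80). Gene ends were less common among list-only peaks: 7.9% of post-caerulein-only peaks (7.2 to 8.5) lay within 1 kb of an end of a protein-coding gene, against 34.3% of shared peaks (33.7 to 34.8). The untreated list gave 8.2% (7.5 to 9.0) and 33.8% (33.3 to 34.3). These shares were not matched on peak width or score, and a wider peak reaches a gene end more readily. They therefore do not show by themselves that list-only regions lie farther from gene ends.

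**Figure D1:**
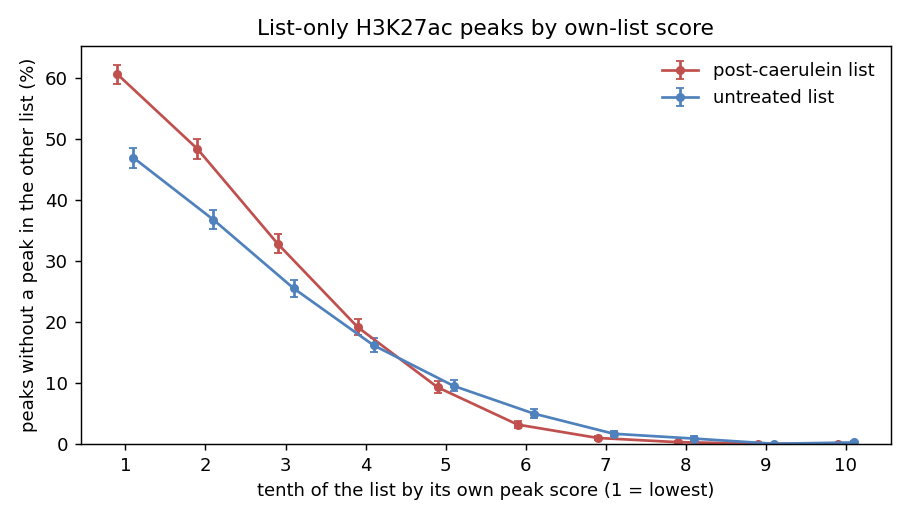
Share of peaks without a peak in the other list (percent, y axis, with exact 95% binomial intervals) in 10 equal groups of peaks ranked by the list's own score (x axis, 1 = lowest), for the post-caerulein and untreated lists, 1 library each. The share went from 60.59% in the lowest group to 0.03% in the highest group of the post-caerulein list, and from 46.92% to 0.29% in the untreated list.

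Single genes gathered many list-only peaks of one condition and none of the other. Slco3a1, an organic anion transporter (chromosome 7, 74275418 to 74554780), had 12 post-caerulein-only peaks, and the H3K27ac-covered length within 50 kb of its ends was 24.1 kb after caerulein and 10.1 kb in untreated spheroids. Tox, an HMG-box transcription factor, had 10 such peaks. Pfkfb3, a regulator of glycolysis, also had 10, with 66.8 kb covered after caerulein and 44.3 kb without treatment. The Ras-family GTPase Rras2, the transporter Slc16a12, Ccbe1 and Zfp827 had 9 each, and the pseudokinase Peak1 and the lipid phosphatase Plpp3 had 8 each. A further gene of the rule is not named here. In the other direction, Prom1 (CD133, a progenitor and duct surface protein; chromosome 5, 43993621 to 44102047) had 10 untreated-only peaks, with 56.9 kb covered after caerulein and 81.8 kb in untreated spheroids. The transcription factor gene Foxo1, the plasma membrane calcium pump gene Atp2b1 and the interferon-inducible Samd9l had 8 untreated-only peaks each. Hopx, a homeodomain gene, and Shoc1 had 7 each. Rptor, a subunit of mTOR complex 1, Arrdc4, Zcchc13 and Ssbp3 had 6 each. Only 4 of the 10 post-caerulein and 6 of the 10 untreated genes kept any list-only peak when peaks under the median score of their list were left out. With a 10 kb assignment limit, 5 of the 10 post-caerulein and 3 of the 10 untreated genes had a difference of 0. Assignment was by nearest gene end, and the peaks of Zcchc13 lay 13008 to 94373 bp from it. Across the genome, 2931 genes had more post-caerulein-only peaks and 2497 had more untreated-only peaks. With the score limit these became 134 and 221.

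**Figure D2:**
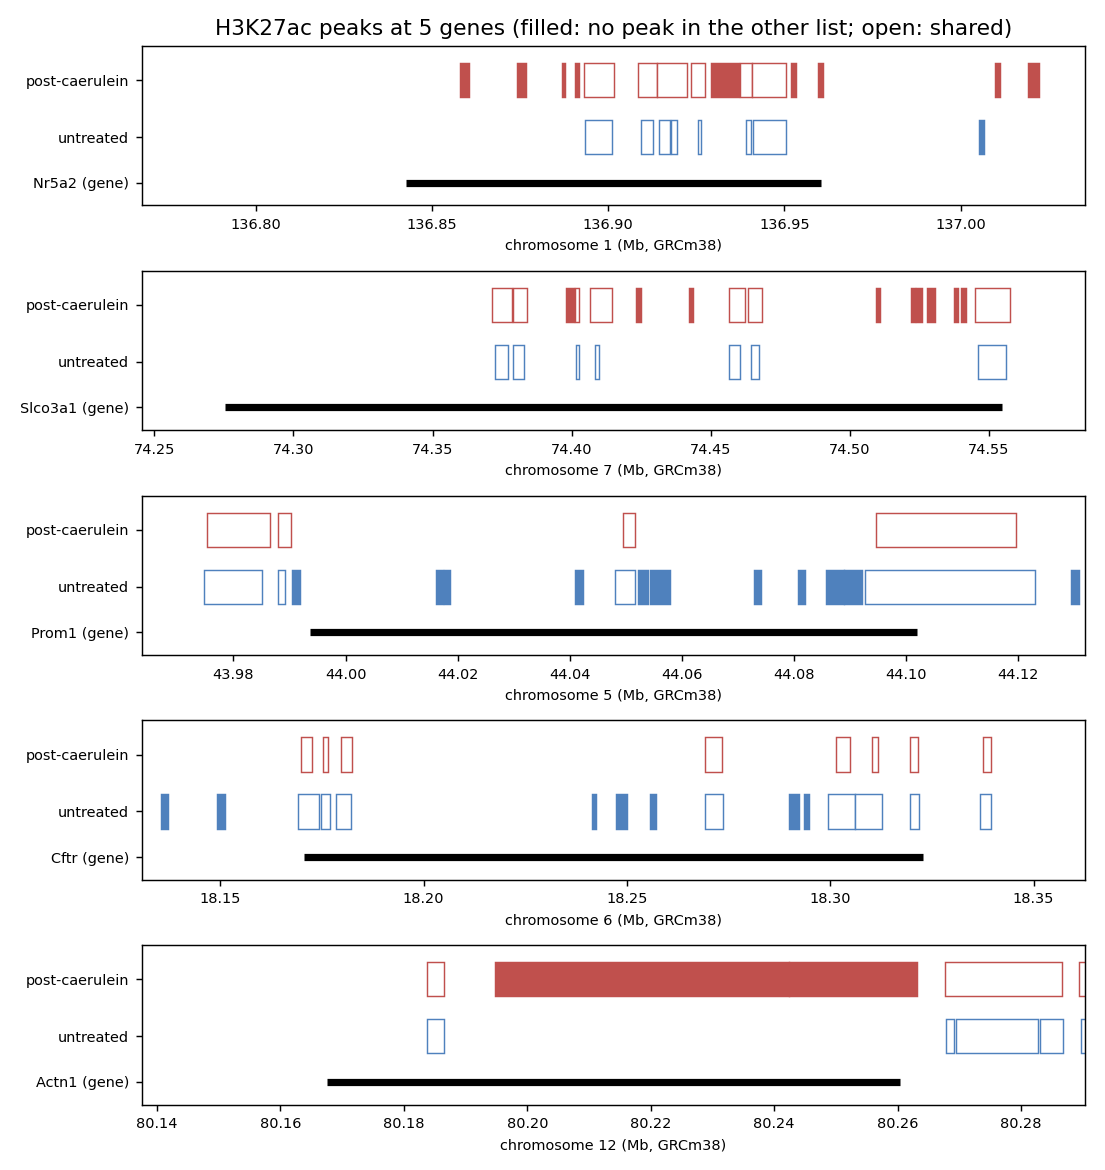
H3K27ac peaks of the post-caerulein and untreated lists (rows) along 5 genes (x axes in Mb of GRCm38; black bar, the annotated gene). Filled boxes have no peak in the other list and open boxes are shared. Prom1 and Cftr carried filled boxes in the untreated row, and Nr5a2, Slco3a1 and Actn1 mainly in the post-caerulein row.

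The highest-scored list-only peaks marked a few strong regions. After caerulein they lay at Csf2ra, a receptor gene for granulocyte-macrophage colony-stimulating factor (chromosome 19, 61224546 to 61228463, score 3100), within Cxxc5, at Hs3st1, a heparan sulfate sulfotransferase gene, at Actn1, which encodes an actin cross-linker, and 132703 bp from the nearest end of Emb. The Actn1 domain was the widest: adjoining peaks of 47.6 and 20.7 kb (chromosome 12, 80194727 to 80263093) fell in a gap of 81.3 kb without any untreated peak. In untreated spheroids the highest-scored list-only peaks lay within Fhl2, a LIM-domain cofactor gene, 57963 bp from the nearest end of Elovl5, within Mrps28, and at Sipa1l3, where a peak of 34.5 kb (chromosome 7, 29480967 to 29515471) lay in a gap of 93.9 kb in the post-caerulein list. Gene ends were marked in both lists for 11583 genes, in the post-caerulein list alone for 405 and in the untreated list alone for 291. For the post-caerulein list alone the rule named Csf2ra, Erg, Fabp4, Fat1 and Lrg1, all tied at a score of 3100. For the untreated list alone it named Pebp4 (score 3178.97), Sipa1l3 (3113.94) and, tied at 3100, Apom and the neighbouring water channel genes Aqp2 and Aqp5. Aqp2 and Aqp5 shared 1 untreated-only peak of 12707 bp. At Erg, Fabp4, Fat1, Lrg1, Pebp4 and Apom the end was marked by a peak that was shared, but only in one list did it come within 1 kb of the end. The widest peaks were mostly common to both lists. Zmiz1 lay under the widest peak of each (93770 bp after caerulein, 92310 bp untreated), and Shb, Bcar3 and Sorbs2 were among the 5 widest of both. Abhd2 (71720 bp) completed the post-caerulein set and Cystm1 (66652 bp) the untreated set.

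The spheroids had a ductal rather than an acinar H3K27ac pattern in both conditions. An end of 21 of 22 ductal genes was marked in both lists, among them Krt19, Krt7 and Sox9, whereas 20 of 24 acinar genes had no marked end in either, including the acinar regulator Ptf1a. Of the 13 digestive enzyme genes in the acinar list, 12 were unmarked at their ends in both lists. The acinar list nevertheless had 15 post-caerulein-only and 2 untreated-only peaks, at percentile 97.56 (sampling error 0.15) of matched random lists. The largest difference was at Nr5a2, a nuclear receptor of the acinar program (chromosome 1, 136842562 to 136960448), which had 9 post-caerulein-only peaks and 1 untreated-only peak and a marked end after caerulein alone. Without Nr5a2 the list was at percentile 87.30. It also did not stand apart with the score limit (93.0), without an assignment limit (96.96), by nearest gene body (96.93) or by covered length (83.41). Prss2, a trypsinogen gene in a family of near-identical copies and therefore uncertain, had 3 post-caerulein-only peaks, and Mecom had 2. In all, 4 acinar genes had more post-caerulein-only peaks, 1 had more untreated-only peaks and 19 were even.

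Ductal genes differed in both directions. More post-caerulein-only peaks were found at 8 genes, such as the osteopontin gene Spp1 (3 against 0) and the bicarbonate cotransporter gene Slc4a4 (9 against 6), and more untreated-only peaks at 5, led by Prom1 (0 against 10) and the chloride channel gene Cftr (0 against 6; 20.1 kb covered after caerulein and 45.8 kb untreated). The list mean leaned to the untreated side (-0.273 peaks per gene) although more genes leaned the other way, and it was at percentile 9.64. Without Prom1 the list was at percentile 45.58. The list was at 54.44 with the score limit, 60.48 with a 10 kb assignment limit and 74.15 by covered length. Of the metaplasia and progenitor genes, 10 had more post-caerulein-only and 7 more untreated-only peaks (percentile 59.00). Notch2 (5 against 0) and the Notch target Hes1 (3 against 0) were on the post-caerulein side. Ly6a (0 against 3) and Agr2 (0 against 2) were on the untreated side. Covered length was close at Hes1 (48.2 kb after caerulein, 47.2 kb untreated), whereas at Notch2 it was 59.4 and 46.3 kb. The Hes1 peaks lay 13314 to 82742 bp from its ends, partly outside the 50 kb used for covered length. The gastric trefoil factor genes Tff1 and Tff2, named after their values were seen, were the 2 genes of this list marked at an end after caerulein alone.

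Markers of other cell types were mostly unmarked in both lists. No end was marked for 20 of 22 endocrine, 19 of 20 mesenchymal, 15 of 20 immune and 12 of 16 endothelial genes. Nkx6-1, an endocrine regulator, had 2 post-caerulein-only peaks at the gene. The 2 untreated-only peaks assigned to Neurod1 lay 52986 and 61338 bp from it, and no peak of either list lay within 50 kb of its ends. Pdgfrb, Tcf21 and Cspg4 had 1 post-caerulein-only peak each, which were the 3 list-only peaks of the mesenchymal list (percentile 93.90). With equal numbers of peaks in the lists, Cspg4 turned to the untreated side (-1) and the list was at percentile 73.05, whereas by covered length it stood apart (98.85). Ptprc and Cd14 had 1 post-caerulein-only peak each and Spi1 had 1 untreated-only peak. Tek had 2 untreated-only peaks, Cdh5 and Cldn5 1 each, and Eng 1 post-caerulein-only peak. In all, the endothelial list had 7 post-caerulein-only and 9 untreated-only peaks. Of its genes, 3 leaned to the post-caerulein side, among them Erg (2 against 1), and 4 to the untreated side. The endocrine, immune and endothelial lists were at percentiles 27, 68.24 and 23.38. Housekeeping genes were marked in both lists for 19 of 20, with 0 post-caerulein-only and 3 untreated-only peaks, of which Tbp had 2 and Polr2a 1 (percentile 18.86).

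Signalling lists had more post-caerulein-only than untreated-only peaks, but so did matched random genes, and none of these lists stood apart. With no assignment limit, the AP-1 (99.82) and epithelial-mesenchymal transition (98.12) lists did. Of 30 EGFR-MAPK genes, 10 leaned to the post-caerulein side, among them Ets1 (5 against 1), Ets2 and the pathway inhibitor Spry1 (3 against 0 each) and Spred2 (4 against 1), and 7 to the untreated side (percentile 69.34). Of 20 AP-1 and immediate early genes, 5 leaned to the post-caerulein side, with Jun at 3 against 0, Klf6 at 5 against 2, Myc at 3 against 1 and Ier5 at 2 against 0. Only 1 leaned the other way, and 14 were even, among them Fos, Fosl1, Junb and Egr1 (percentile 82.56). NF-kB and cytokine genes split into 9 and 3. Tnfaip3, an inhibitor of NF-kB signalling, had 5 against 1 and the chemokine gene Cxcl5 3 against 0. Birc3 had 2 against 0 and Csf1 0 against 2 (percentile 77.61). Covered length did not differ at Csf1 (30.7 kb after caerulein, 30.6 kb untreated), whereas at Birc3 it was 28.4 and 15.0 kb. Wnt and Hippo genes split into 9 and 3 (percentile 80.20). Tead1 (5 against 0), Wnt7a and Wnt7b (4 against 0 each) stood opposite Tcf7l2 (0 against 4). Covered length was close at Tead1 (61.6 kb after caerulein, 60.3 kb untreated), whereas at Wnt7a it was 31.9 and 16.0 kb. The Tead1 peaks lay 17538 to 88318 bp from its ends, partly outside the 50 kb used for covered length. The epithelial-mesenchymal transition list split into 11 and 4 (percentile 92.94). Itgb6 (5 against 0), Ccn1 (4 against 0) and the fibronectin gene Fn1 (3 against 0) stood opposite the receptor gene Tgfbr2 (1 against 6). Some of these counts rested on weak peaks, with scores of 57.51 to 99.53 at Jun, 62.08 to 73.56 at Cxcl5 and 73.99 to 97.19 at Fn1. The post-caerulein list had a lowest score of 50.01 and a median of 526.37. Ets1 had a peak above that median (877.28).

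Interferon and STAT genes leaned to the post-caerulein side at 5 genes and to the untreated side at 8 (percentile 50.50). The receptor chain gene Ifngr1 and the kinase gene Jak1 had 5 post-caerulein-only peaks each and no untreated-only peak, whereas the interferon-induced Oasl2 and Bst2 had 2 untreated-only peaks each. The unfolded protein response list split into 4 and 4 (percentile 28.64). The chaperone gene Canx was at 0 against 3 and Pdia6 at 0 against 2. Sesn2 was at 2 against 0 and Asns at 1 against 0. Covered length at Canx went slightly against its peaks (23.8 kb after caerulein, 22.4 kb untreated), whereas at Pdia6 it was 2.5 and 6.2 kb. It was close at Sesn2 (53.2 and 50.0 kb) and Asns (3.6 and 3.2 kb). The cell cycle list split into 6 and 4 (percentile 29.86). The neighbouring inhibitor genes Cdkn2a and Cdkn2b had 4 and 2 untreated-only peaks, and Ccnd1 and Aurka had 2 and 1 post-caerulein-only peaks. Covered length was close at Ccnd1 (45.5 kb after caerulein, 43.6 kb untreated) and slightly against the peaks at Aurka (8.3 and 9.2 kb). It went with the peaks at Cdkn2a (11.2 and 18.2 kb) and Cdkn2b (19.3 and 25.6 kb). All 22 unfolded protein response genes and all 24 cell cycle genes were marked at an end in both lists.

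**Figure D3:**
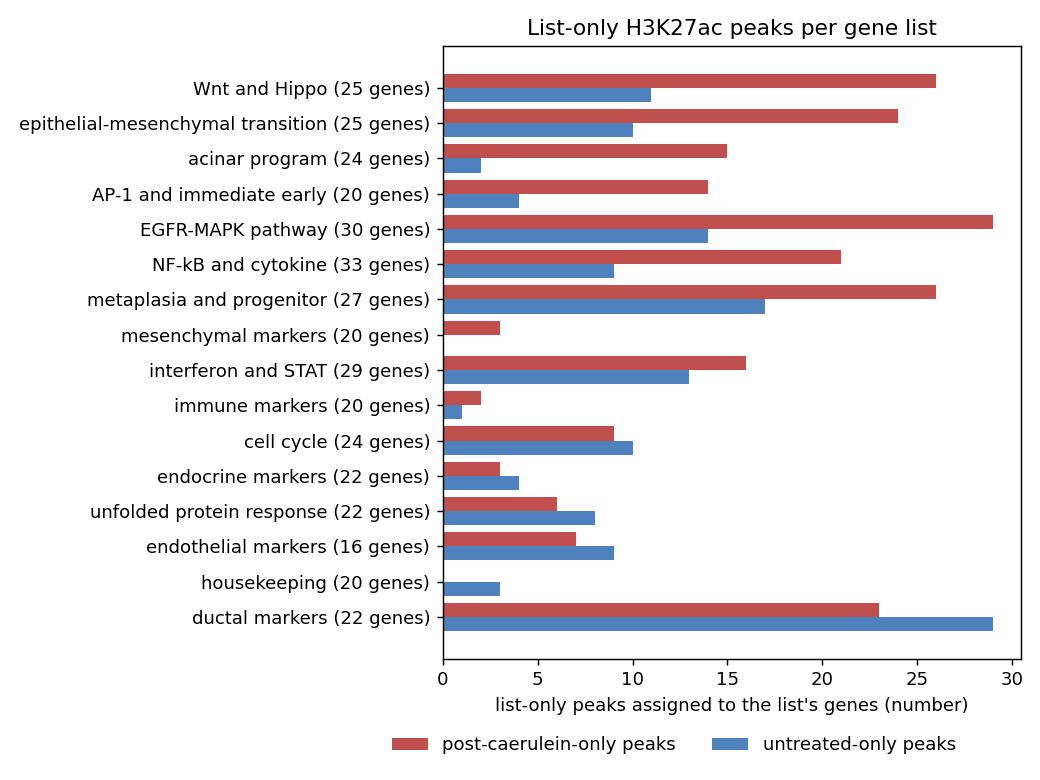
Number of post-caerulein-only and untreated-only H3K27ac peaks (x axis) assigned to the genes of 16 lists (y axis, with the number of genes measured), ordered by the mean difference per gene, 1 library per condition. The acinar list (15 against 2) was the only one that stood apart from matched random lists, narrowly and not under every alternative. By chance 0.8 of the 16 lists would stand apart. The ductal list had more untreated-only peaks (23 against 29).

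The X chromosome stood apart from the autosomes. Genome-wide, 55.7% of list-only peaks were post-caerulein-only (exact 95% interval 54.8 to 56.6), and the autosomes ranged from 51.3% on chromosome 4 to 61.2% on chromosomes 8 and 13. On X, 111 post-caerulein-only and 173 untreated-only peaks gave 39.1% (33.4 to 45). The Y chromosome had 4 peaks in each list, all shared, at Kdm5d, Eif2s3y, Uty and Ddx3y.

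**Figure D4:**
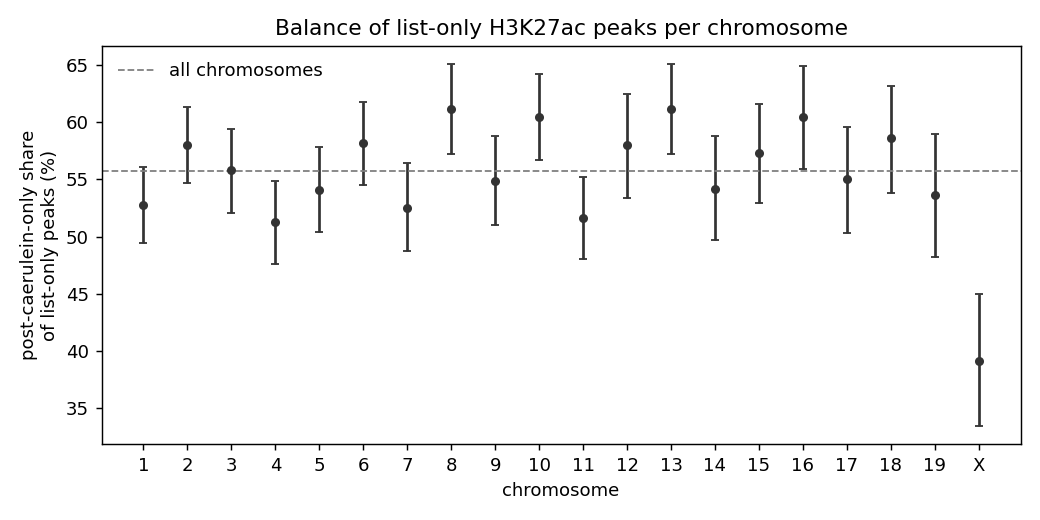
Post-caerulein-only share of all list-only peaks (percent, y axis, with exact 95% binomial intervals) per chromosome (x axis), with the genome-wide share of 55.7% as a dashed line. X, at 39.1%, is the only chromosome whose interval lies below 50%; Y has no list-only peak and is not drawn.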

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

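The nearest-gene-body assignment, the runs without a list's leading gene, and the 1 kb tolerance for gene lists were chosen after seeing the data; the other alternatives were planned. With list-only peaks held to their own list's median score, 183 post-caerulein-only and 304 untreated-only peaks remained (shares of 0.94% and 1.61%), the difference between them reversed from 1390 to -121, and genes leaning to each side numbered 134 and 221. Under that limit the X share was 22.2% (2 and 7 peaks, too few to set apart from 37.6% genome-wide), and gene-end shares were 10.4% and 10.2%. The shares of post-caerulein-only and untreated-only peaks were 20.1% and 16.2% when 50% of a peak had to be covered, 14.7% and 12.5% when a peak within 1 kb counted as shared, 15.5% and 13.2% after merging within 1 kb (difference 788), and 16.2% and 15.0% with equal numbers of highest-scored peaks (difference 444). A gene-end window of 2.5 kb gave gene-end shares of 12.4% and 13.6%. A 10 kb assignment limit left 1754 and 1587 leaning genes. The acinar list no longer stood apart with the score limit (93.0), no assignment limit (96.96), nearest gene body (96.93), covered length (83.41) or without Nr5a2 (87.3). Lists that came to stand apart were AP-1 (99.82) and epithelial-mesenchymal transition (98.12) with no assignment limit, the mesenchymal markers by covered length (98.85) and, without matching, AP-1 (97.8), EGFR-MAPK (99.16), epithelial-mesenchymal transition (99.16) and Wnt and Hippo (99.54). The cause of these changes was not tested. Of 96 named genes checked, the direction reversed for 1, Cspg4 (-1 with equal numbers of peaks). No paired analysis was possible because each condition has 1 library, and for the same reason no library could be left out. Unknown depth limits every count of list-only peaks, since most lie near the caller's threshold. The planned motif comparison was not run.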

Other observations

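The tests of runs and of wide domains were chosen after the result was seen. Those of the acinar list and of the X chromosome were written once these patterns were known but before the tested values were. Tests were run on 4 patterns with 7 explanations, and all 7 are given. The 2 acinar tests had been set aside after their results were seen, when the test of wide domains was added, and were then put back unchanged.

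Counting the genes named by rule, 76 genes had at least 5 post-caerulein-only peaks and no untreated-only peak, and 46 had the opposite. The following genes were picked from these after their values were seen. On the post-caerulein side were the hypoxia factor gene Hif1a (8 peaks), the glucocorticoid receptor gene Nr3c1 (7), the chromatin protein gene Hmga2 (7; 51.7 kb covered after caerulein against 18.8 kb untreated), the caveolin gene Cav2 (7), the transcription factor genes Klf7 and Zfp462 (6 each) and Zbtb16 (5), and the growth factor receptor gene Fgfr2 (5). On the untreated side were the homeobox gene Barx2 (6), the cytokine receptor gene Il20rb (6), Ceacam12 (6; 0.0 kb covered after caerulein against 13.9 kb untreated), the transcription factor genes Sox13 (5; 7.8 against 35.4 kb) and Cux1 (5), the ephrin receptor gene Epha2 (5) and the angiogenic factor gene Vegfa (5).

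Within the interferon and STAT list, members that leaned to the untreated side were mainly induced genes (Oasl1, Oasl2, Bst2, Irf9, Ifit2 and Gbp3), beside the receptor genes Il6st and Ifnar2. Those that leaned to the post-caerulein side were Ifngr1, Ifngr2, Jak1, Il6ra and Socs3. This split was noticed in the data and was not tested.

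Runs of list-only peaks at single genes were more frequent than independent calls near the threshold would give: 122 genes had at least 5 list-only peaks, all of one list, against at most 22 in 100 random reassignments of the list-only peaks. On the untreated side 46 genes had such runs and reassignment gave at most 8, but neighbouring weak peaks in 1 domain are not independent, so this does not decide whether the post-caerulein list was merely more sensitive. A run may be a single stronger or broader domain called in pieces. Local copy number in a culture, variation between cultures and an effect of the earlier caerulein treatment stay open and untested, since each condition has 1 library.

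Without Nr5a2 the acinar list was at percentile 87.3 and no longer stood apart. The full list lay so close to the limit (97.56) that leaving out its leading gene had to end the call, so whether 1 gene carries the list stays open. Acinar cells kept in the post-caerulein culture are argued against by the digestive enzyme genes, of which 0 of 13 (among them Cpa1, Cela1, Pnlip and Prss2) had a gene-end peak in the post-caerulein list alone. A small share of acinar cells, below what a peak caller detects, is not excluded. Whether Nr5a2 itself differs because of caerulein stays open and untested.

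Wide list-only peaks of at least 15 kb lay at Actn1 (2), Hs3st1, Actl7b and Sipa1l3. Of 221 peaks of at least 30 kb in the lists together, 1.81% (exact 95% interval 0.5 to 4.57) had under 50% of their length covered by the other list, against 4.35% (3.99 to 4.73) of peaks of 5 to 15 kb. Peaks without any cover were 0.9% (0.11 to 3.23) and 0.88% (0.72 to 1.07), and for peaks of 15 to 30 kb the shares were lower, 0.91% (0.45 to 1.61) and 0.25% (0.05 to 0.72). A wider peak also meets a peak of the other list more readily, so the shares leave open whether the peak caller loses wide regions in 1 library.

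The X chromosome's lean to untreated-only peaks did not rest on its leading loci alone. Without Fundc1, Zcchc13 and Clcn5, the post-caerulein share was 41.7% (35.7 to 47.9), still under the genome-wide 55.7%. Without Dock11 and Nhsl2 as well, which tie with Clcn5 at 5 untreated-only peaks, it was 43.4% (37.2 to 49.7). These intervals count each peak as independent, although list-only peaks came in runs at single genes, and may be too narrow. A lean carried by more clusters of peaks is not excluded. Peaks matched 1 to 1 between the lists were also slightly narrower after caerulein on X, with a median log2 width ratio of -0.017 (bootstrap 95% interval -0.041 to -0.002), while the lowest autosome, chromosome 7, had 0.005 (-0.004 to 0.017), and the intervals of the 2 touch. A lower X dosage in the post-caerulein culture is a candidate explanation that goes with this value. A larger male share, which would also bring more Y signal, found no support in the 4 matched Y peaks (-0.202, -0.313 to 0.173), which are too few to exclude it. The width ratio cannot separate it from any other lower H3K27ac signal along X. An effect of caerulein stays open and untested.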
